A study of Homo sapiens with 24 samples.

How the data were processed

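Cells were THP1 monocytes, wild type or CD33 knockout, transduced with lentivirus made in HEK-293FT cells that carried either empty pLKO.1 (shCTRL) or a hairpin against PTPN6 (shPTPN6). Per the labels, cells met the virus for 24 hours, rested for 48 hours, were selected with 1 µg/ml puromycin, and were differentiated with 10 ng/ml PMA for 48 hours and 48 hours without it. Libraries were made from 100 ng of total RNA with a kit that reads the 3' ends of polyadenylated RNA, so a gene is counted near its end regardless of its length. The values are raw read counts per gene and library, as the authors deposited them, with no normalization. The submitters' processing notes name bcl2fastq, STAR 2.7.3a, featureCounts (Subread 2.0.0), the hg38 genome, R 3.6.1 and DESeq2 1.26.0, without roles, order or parameters. Annotation release, strand setting and any treatment of duplicate reads are not stated. An unstranded count would add antisense and overlapping transcripts to a gene, and a count without removal of duplicates would add to the spread of abundant short tags.

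Of 24 labelled samples 23 were used. CD33KO_shPTPN6 replicate 2 was not used here. Library totals ran from 2024032 to 6269304; most knockout libraries held fewer than the wild-type ones, so a gene at 5 CPM has about as few as 10 counts in them. Of 60617 gene identifiers 60261 (99.41%) matched a symbol, and 34700 had at least 1 count. Positions and overlaps came from gencode release 29, which may differ from the release used for counting.

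Analysis was done in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16 by group, which left 13098, and libraries were scaled by TMM. A single model with a mean per group was fitted to all 23 libraries (estimateDisp, robust glmQLFit), and 6 contrasts were tested with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. They are CD33 knockout with control vector, PTPN6 knockdown in wild type, both together against WT_shCTRL, PTPN6 knockdown in the knockout, CD33 knockout with knockdown, and the interaction, which is the knockdown effect in the knockout minus that in wild type. Means ± SD are TMM-scaled CPM over the libraries of a group. Fold changes are log2 with an SE derived from the test, as the absolute log2 fold change over the square root of its F statistic. This SE is approximate, above all for very large changes and genes near 0 in a group, and does not by itself give the p-value. The target genes were also compared with a two-sided exact permutation test of log2 CPM. A fold against a group at 0 in every library is given as a lower bound against 3 counts summed over the group.

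The groups, contrasts, tests, 35 gene lists, alternatives and the rule for named genes were fixed before the data were examined. Lists cover signalling, inflammatory, interferon, lipid, metabolic, stress, proliferation, differentiation and ribosomal genes and markers of other cell types, and CD33 and PTPN6 are in none. Some lists share members, so called lists are not all separate findings. Another list also held 19 of 32 macrophage maturation, 16 of 26 lipid-associated macrophage and 14 of 25 alternative activation genes. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 35 lists of a contrast, and again with the correlation estimated from the residuals. Camera asks whether a list moved more than the other genes. Counts adjusted over the list alone are given where they differ from those adjusted over all genes.

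Named genes were CD33 and PTPN6, the 6 largest rises and 6 largest falls of each comparison with WT_shCTRL among genes with an adjusted p under 0.05, a mean of at least 5 CPM, a symbol and groups that do not overlap, and up to 2 called members per list and direction with the smallest adjusted p, some of which were left out for length or are not reported here. For the interaction they were the 5 smallest adjusted p per direction at 5 CPM or more, and for the other 2 contrasts the 3 largest rises and falls by the same rule. CYBB in the last 3 contrasts is outside this rule.

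Fold changes of the knockout with and without knockdown, and of the knockdown in both lines, come from separate libraries and were compared by correlation across genes and by shared calls. The knockout and the knockdown share the WT_shCTRL libraries, so their comparison was set against 20 simulated draws of unchanged groups and against 20 splits of the controls into 3 and 3. Sums of effects were set against 20 draws simulated without interaction. The pipeline was tested on simulated data with the depth and spread of the knockout contrast. Of 50 genes per step it called 18 at a 1.25-fold change, 30 at 1.5-fold, 45 at 2-fold and 47 at 4-fold, and 5 unchanged genes, 3.45% of all calls. A raised list gave a camera p of 3.82e-54, and 3 of 200 unchanged lists passed 0.05. Simulated genes were drawn independently of each other, so this does not show how often lists with co-varying members are called falsely. Changes under 2-fold were thus often missed in this simulation, where few genes changed. In the knockout contrast itself 56.7% of genes were called, which makes the adjusted threshold less strict. The simulated shares therefore do not carry over to the data.

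Alternatives were DESeq2 1.42.0 size factors and its Wald test, other filters, a replicate block, a model of the compared groups alone, a 2-fold minimum, other list tests and leaving out each replicate. Thinning all libraries to 2024032 counts and leaving out WT_shCTRL 4, WT_shPTPN6 3 and CD33KO_shCTRL 2, or the library of each group with the most genes outside the rest, were added after the data were seen. Other splits of the same libraries, 100 per contrast, were refitted with edgeR.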

Results

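THP1 is a human monocytic leukaemia line whose cells turn into adherent macrophages when treated with the phorbol ester PMA. CD33 is an inhibitory receptor of the Siglec family, and PTPN6 encodes SHP-1, a phosphatase that binds the phosphorylated inhibitory motifs of such receptors. The series crosses CD33 genotype (wild type or knockout) with lentiviral vector (empty pLKO.1 or a hairpin against PTPN6), so it can ask whether losing the receptor and losing the phosphatase change the same genes and whether their effects add up. RNA of PMA-differentiated macrophages was counted at the 3' ends of polyadenylated transcripts. The labels name 24 libraries in 4 groups of 6; CD33KO_shPTPN6 replicate 2 was not analysed here, which leaves 5 libraries in that group and 23 in all.

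Total counts were 4170191 to 5700712 per library in WT_shCTRL, 3318001 to 6269304 in WT_shPTPN6, 2048161 to 3749258 in CD33KO_shCTRL and 2024032 to 2581042 in CD33KO_shPTPN6. Apart from CD33KO_shCTRL replicate 5, every knockout library was shallower than every wild-type library, and 13098 genes had enough counts to be tested in all comparisons. Mitochondrial transcripts took 5.864 to 6.539% of the counts in WT_shCTRL, 7.85 to 8.697% in WT_shPTPN6, 6.526 to 7.13% in CD33KO_shCTRL and 6.359 to 6.545% in CD33KO_shPTPN6. Ribosomal protein transcripts took 6.166 to 7.256%, 9.173 to 9.474%, 4.458 to 4.73% and 7.372 to 7.788% in the same order. The first principal component held 47.9% of the variance, the second 25.7% and the third 5.48%. The labels do not say whether the replicates were separate cultures, so every p-value measures only the spread between these libraries.

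CD33 stood at 47.4, 45.2, 44.3, 47.6, 39.7 and 48.5 CPM (counts scaled to a common library size by TMM) in WT_shCTRL replicates 1 to 6 and at 87.2, 81.3, 88.9, 85.5, 94.7 and 94.9 CPM in WT_shPTPN6. It stood at 22.5, 18.3, 16.2, 22.3, 21.0 and 20.7 CPM in CD33KO_shCTRL and at 23.7, 23.8, 15.7, 25.3 and 29.03 CPM in CD33KO_shPTPN6 replicates 1, 3, 4, 5 and 6. CD33 was thus 55.4% lower in the knockout with control vector (log2 fold change -1.16 ± 0.10 SE, edgeR adjusted p = 3.31e-19, exact permutation p = 0.00216, the smallest the groups allow). Knockdown of PTPN6 in wild type raised CD33 by 0.97 ± 0.07 (edgeR adjusted p = 4.95e-23), whereas in the knockout the estimate was 0.22 ± 0.13 (edgeR adjusted p = 0.185; 0.0343 without replicate 4, and up to 0.548 over the alternatives). The labels do not place the edit within CD33, and 3' end counts outside an edit check nothing about it, so the remaining CD33 counts neither show nor exclude a protein.

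PTPN6 stood at 35.8, 43.9, 49.5, 46.8, 39.5 and 52.4 CPM in WT_shCTRL and at 10.5, 8.73, 9.33, 12.8, 11.1 and 10.96 CPM in WT_shPTPN6, replicates 1 to 6. It stood at 35.7, 38.5, 36.4, 44.1, 39.1 and 32.6 CPM in CD33KO_shCTRL and at 4.94, 7.31, 7.63, 11.8 and 5.32 CPM in CD33KO_shPTPN6 replicates 1, 3, 4, 5 and 6. The hairpin therefore lowered PTPN6 by 76.3% in wild type (log2 fold change -2.08 ± 0.11, edgeR adjusted p = 2.07e-33) and by 80.6% in the knockout (-2.37 ± 0.17, edgeR adjusted p = 2.08e-24), without overlap between groups in either. PTPN6 was also lower in the knockout with control vector (-0.23 ± 0.10, edgeR adjusted p = 0.0372, exact permutation p = 0.0498), with overlapping libraries. That small call was lost with DESeq2 (adjusted p = 0.0747) and without replicate 3 (0.118) or 6 (0.203), over a range of 0.0217 to 0.203. The hairpin target CGACATGCTCATGGAGAACAT spans 21 bases on chromosome 12, positions 6959963 to 6959983 on the plus strand (GRCh38), in the coding sequence of PTPN6 in exon 12 of 16 of the full-length transcripts. An exact match to it was found in 7 annotated transcripts, all of PTPN6.

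**Figure D1:**
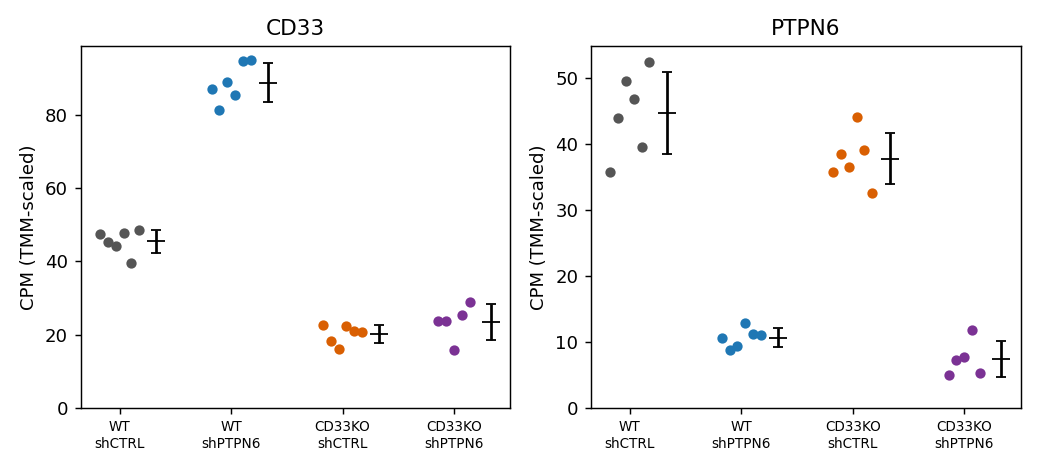
CPM (TMM-scaled) of CD33 and PTPN6 in each library of the 4 groups; points are libraries, the bar beside them is the mean and the whiskers 1 SD. PTPN6 lay between 4.94 and 12.8 CPM in every shPTPN6 library and between 32.6 and 52.4 CPM in every shCTRL library.

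In macrophages with the control vector, CD33 knockout libraries held more inflammatory transcripts and fewer interferon-response, Siglec and Alzheimer's disease risk transcripts than wild type (n = 6 and 6; the interferon list had an adjusted p of 0.0565 with an estimated correlation). All 28 tested NF-kB feedback and target genes rose, with a median log2 fold change of 1.33 (camera adjusted p = 3.81e-18). Of 30 cytokines and chemokines 23 rose and 5 fell (23 and 6 adjusted over the list alone), with a median of 3.23 (camera adjusted p = 1.29e-12). IL23A, a subunit of interleukin 23, went from 8.22 ± 0.67 to 292 ± 21.2 CPM (mean ± SD), and IL1RN, the interleukin 1 receptor antagonist, from 327 ± 16.2 to 2104 ± 86.4 CPM. PTGS2, the inducible cyclooxygenase, rose by 4.26 ± 0.10 (log2 ± SE, edgeR adjusted p = 2.86e-64) and the survival factor BCL2A1 by 3.24 ± 0.06 (edgeR adjusted p = 2.99e-72). Here and in the 2 comparisons that follow, the libraries of the compared groups did not overlap for any gene given with a value, except PTPN6 in the knockout with control vector.

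Type I interferon response genes fell in 43 of 45 cases and rose in none, with a median of -1.01 (camera adjusted p = 6.57e-15; adjusted p = 0.0565 with an estimated correlation). OAS1, which makes the activator of RNase L, fell by 1.79 ± 0.07, and the antiviral membrane protein IFITM3 fell by 1.39 ± 0.05 (edgeR adjusted p = 1.24e-44 and 3.83e-36). Of 18 Siglecs and other inhibitory receptors 13 fell and 3 rose (camera adjusted p = 0.00177). CD22 went from 59.3 ± 3.30 to 6.50 ± 1.76 CPM and SIGLEC15 from 30.5 ± 1.80 to 1.36 ± 0.69 CPM, while PECAM1 rose from 162 ± 8.34 to 368 ± 16.9 CPM. Among 30 genes at Alzheimer's disease risk loci 18 fell and 5 rose (19 and 5 adjusted over the list alone; camera adjusted p = 0.000575). BIN1, a membrane-curving protein, fell by 3.81 ± 0.08, the sorting receptor SORL1 fell by 3.46 ± 0.10, and TREM2, a lipid-sensing receptor, fell by 1.52 ± 0.05 (edgeR adjusted p = 5.38e-70, 2.14e-58 and 2.97e-52).

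Phagocytic receptors and uptake genes fell in 21 of 36 cases and rose in 9 (22 and 10 adjusted over the list alone; camera adjusted p = 0.0379). The scavenger receptor SCARB1 fell by 1.97 ± 0.09, while CD36, another scavenger receptor, rose by 1.68 ± 0.05 (edgeR adjusted p = 1.03e-38 and 4.29e-54). Of 11 NADPH oxidase genes 3 were higher and 4 lower, and the list was not called (camera adjusted p = 0.761). Its members included CYBB, the catalytic subunit of the phagocyte oxidase, which fell from 173 ± 8.30 to 20.2 ± 3.16 CPM, and NCF4, a cytosolic subunit, which fell from 131 ± 4.17 to 40.5 ± 2.14 CPM. Cholesterol synthesis genes fell in 14 of 23 cases and rose in 4 (15 and 4 adjusted over the list alone; camera adjusted p = 0.000969).

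Other groups rose in the knockout. Heat shock genes rose in 14 of 15 cases and fell in 1 (camera adjusted p = 7.05e-06), HSPA1B by 2.51 ± 0.09. Early response genes of the ERK and AP1 pathway rose in 19 of 30 and fell in 5 (camera adjusted p = 4.23e-06), with the phosphatases DUSP2 and DUSP5 at log2 fold changes of 2.74 and 2.09. Adhesion and matrix genes rose in 23 of 34 and fell in 6 (25 and 6 adjusted over the list alone; camera adjusted p = 2.67e-07). The matrix metalloproteinase MMP7 went from 39.7 ± 2.77 to 595 ± 31.2 CPM and the collagen receptor ITGA1 from 4.84 ± 1.11 to 182 ± 9.05 CPM. Antioxidant and NRF2 target genes rose in 10 of 20 and fell in 6 (camera adjusted p = 0.0111; adjusted p = 0.164 with an estimated correlation), and FTH1, the ferritin heavy chain, went from 1912 ± 83.8 to 7291 ± 439.9 CPM. Glycolysis and hypoxia genes rose in 18 of 31 and fell in 9 (camera adjusted p = 0.0386; adjusted p = 0.211 with an estimated correlation), NDRG1 by 2.22 ± 0.05.

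Differentiation markers moved with genotype as well. Markers of undifferentiated myeloid progenitors fell in 10 of 11 cases and rose in 1 (camera adjusted p = 0.000519), with the ribonuclease RNASE2 at -3.00 ± 0.11 and the receptor FLT3 at -2.15 ± 0.12. Macrophage maturation genes rose in 21 of 31 and fell in 8 (camera adjusted p = 0.00035). The secreted glycoprotein CHI3L1 rose by 1.55 ± 0.04, whereas CSF1R, the receptor for macrophage colony-stimulating factor, fell by 1.08 ± 0.05. Ribosomal protein genes fell in 33 of 36 and rose in none (camera adjusted p = 3.93e-11; adjusted p = 0.156 with an estimated correlation), matching the lower share of ribosomal protein counts in these libraries. No list of other cell types was called. Fibroblast and endothelial markers were higher for 6 of 12 and lower for 1 (camera adjusted p = 0.0651), with the endothelial kinase TIE1 at 5.51 ± 1.18 and 49.1 ± 3.82 CPM. Epithelial and HEK-293 markers were higher for 4 of 7 and lower for 2 (camera adjusted p = 0.218), with the cadherin CDH2 at 14.3 ± 1.94 and 63.9 ± 6.16 CPM and the neurofilament INA at 17.4 ± 3.04 and 0.276 ± 0.227 CPM. Median, mean and test differed in sign for the MHC class II, MHC class I and alternative activation lists, which were not called (camera adjusted p = 0.838, 0.818 and 0.999).

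The largest rises separated the lines almost completely. HSPG2, which encodes the basement membrane proteoglycan perlecan, went from 23.3 ± 11.5 to 11979 ± 1940.3 CPM. The growth factor gene NRG4 (log2 fold change 10.06 ± 0.25), the cadherin CDH13 (9.82 ± 0.24) and the pseudogene RPS26P52 (10.39 ± 0.23) were also abundant in every knockout library. Of the wild-type libraries WT_shCTRL replicate 4 stood apart, with HSPG2 at 46.6 CPM where the other 5 of its group lay between 16.9 and 20.5. LINC01287 was at least 241-fold higher and the retroviral envelope gene ERVW-1 at least 119-fold higher, against wild-type groups at 0. The keratin KRT9 was at least 53.2-fold lower. The dipeptidase DPEP1 fell by 7.19 ± 0.18, the acute-phase protein SAA1 fell by 6.88 ± 0.19 and SLFN12 fell by 6.75 ± 0.47. SLFN12 was at 0 in CD33KO_shCTRL except in replicate 3 (0.45 CPM), so its fold rests on very few counts. CLIC5 fell by 6.32 ± 0.21 and BBOX1, an enzyme of carnitine synthesis, fell by 6.16 ± 0.30. Because the strand setting of the counting is not stated, counts of genes that overlap another transcribed gene are uncertain. This holds for NRG4, RPS26P52 (also a copy of RPS26), ERVW-1, ITGA1, FTH1, CSF1R, TAP1, LIPA, MT-ATP6, HK2, CYP1B1, DMP1, TGFB1, SQSTM1, CCND1 and BMP8B. ITGA1 overlaps PELO, MT-ATP6 overlaps MT-ATP8 and MT-CO3, and BMP8B overlaps OXCT2 on the same strand, which no strand setting would separate.

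In this comparison 3711 genes were higher and 3717 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), or 56.7% of those tested. With a change of at least 2-fold also required, 1018 were higher and 1037 lower. The groups did not overlap for 34.1% of tested genes, where chance gives 0.216%. Of 35 lists 15 were called, 8 higher and 7 lower, and 11 of them with an estimated correlation. CD33KO_shCTRL replicate 2 stood apart from the rest of its group by at least 2-fold in 60 genes, against 0 to 43 in the other 22 libraries.

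PTPN6 knockdown in wild type lowered the interferon response and raised genes of lysosomes, metabolism and macrophage maturation (n = 6 and 6). All 45 tested type I interferon response genes fell, with a median log2 fold change of -1.84 (camera adjusted p = 1.19e-26). XAF1 fell by 1.96 ± 0.06 on the log2 scale. Genes of MHC class I presentation fell in 10 of 18 cases and rose in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000395), with the peptide transporter TAP1 at -1.97 ± 0.06. ERK and AP1 early response genes fell in 20 of 30 and rose in 7 (camera adjusted p = 0.000104; adjusted p = 0.0635 with an estimated correlation). The transcription factor EGR1 fell by 2.32 ± 0.10 and EGR2 fell by 1.31 ± 0.07 (edgeR adjusted p = 1.01e-40 and 3.59e-34).

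Lysosome genes rose in 28 of 42 and fell in 5 (camera adjusted p = 3.75e-06), among them the protease CTSH (66.4 ± 7.34 to 221 ± 7.84 CPM) and the acid lipase LIPA (208 ± 7.84 to 474 ± 11.7 CPM). NADPH oxidase genes rose in 8 of 11 and fell in 2 (camera adjusted p = 0.00234). CYBB rose by 1.77 ± 0.05 and S100A8, a calcium-binding protein that activates the oxidase, by 2.73 ± 0.06 (edgeR adjusted p = 3.79e-59 and 3.36e-49). Antioxidant and NRF2 targets rose in 17 of 20 and fell in 2 (camera adjusted p = 8.7e-07), with the ferritin chains FTL at 1.23 ± 0.04 and FTH1 at 1.04 ± 0.05. Glycolysis and hypoxia genes rose in 22 of 31 and fell in 4 (camera adjusted p = 4.24e-07), hexokinase HK2 by 1.82 ± 0.07 and NDRG1 by 1.49 ± 0.05. Cholesterol synthesis genes rose in 16 of 23 and fell in 4 (17 and 4 adjusted over the list alone; camera adjusted p = 0.00167), with the sterol oxidase MSMO1 at 1.78 ± 0.06.

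Siglecs and inhibitory receptors rose in 12 of 18 cases and fell in 3 (camera adjusted p = 0.0068; adjusted p = 0.0548 with an estimated correlation). SIRPA, which binds CD47 and recruits SHP-1, rose by 1.30 ± 0.05, while CD22 fell by 3.25 ± 0.12. Macrophage maturation genes rose in 22 of 31 and fell in 5 (camera adjusted p = 1.16e-05). MMP9, a gelatinase, went from 387 ± 37.7 to 1874 ± 113 CPM and the apolipoprotein APOC1 from 15.8 ± 2.11 to 130 ± 9.62 CPM. Lipid-associated macrophage genes rose in 16 of 25 and fell in 7 (camera adjusted p = 0.0171; adjusted p = 0.112 with an estimated correlation). Cytokines and chemokines rose in 17 of 30 and fell in 7 (camera adjusted p = 0.0352; adjusted p = 0.195 with an estimated correlation), with IL1B at 1.43 ± 0.06 and TGFB1 at -1.16 ± 0.08. The NF-kB list, called in the knockout, was not called here (13 higher and 7 lower of 28, 15 and 9 adjusted over the list alone; camera adjusted p = 0.2). Proliferation genes fell in 28 of 42 and rose in 1 (camera adjusted p = 0.000104), the mitotic activator CDC20 by a log2 fold change of -1.24 and the kinetochore protein CENPF by -0.89.

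Transcripts encoded by the mitochondrial genome rose in 15 of 15 cases (camera adjusted p = 3.07e-08; adjusted p = 0.0548 with an estimated correlation), with MT-ATP6 at 0.92 ± 0.04, beside the higher mitochondrial share of these libraries. Nuclear genes of oxidative phosphorylation rose in 23 of 36 and fell in 1 (camera adjusted p = 1.14e-05; adjusted p = 0.135 with an estimated correlation). Ribosomal protein genes rose in 35 of 36 (camera adjusted p = 2.12e-16; adjusted p = 0.0548 with an estimated correlation), with RPS19 at 0.88 ± 0.04. Alzheimer's disease risk genes fell in 14 of 30 and rose in 8 (camera adjusted p = 0.0352). BIN1 fell by 4.27 ± 0.08, whereas SPI1, the myeloid master regulator PU.1, went from 64.1 ± 7.72 to 152 ± 9.89 CPM. Lymphoid markers fell in 5 of 7 and rose in 1 (camera adjusted p = 0.0171). GNLY, the cytotoxic peptide granulysin, went from 349 ± 34.1 to 8.87 ± 1.22 CPM and the T cell receptor gene TRAC from 313 ± 19.1 to 175 ± 14.1 CPM. Median, mean and test differed in sign for the phagocytosis, integrated stress response and progenitor lists, which were not called (camera adjusted p = 0.585, 0.658 and 0.519).

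The largest rises were in BPI, an antibacterial granule protein (log2 fold change 6.72 ± 0.43), the lectin FCN1 (4.91 ± 0.16) and the decoy receptor IL1R2 (4.69 ± 0.12). CYP1B1 (4.44 ± 0.09), CYP27A1 (4.16 ± 0.24) and CDCP1 (4.04 ± 0.09) followed. BPI was at 0 in WT_shCTRL except in replicate 4 (0.337 CPM), so its fold rests on very few counts. NRAP fell by 6.83 ± 0.26, GRM4 fell by 6.53 ± 0.17, DMP1 fell by 5.87 ± 0.17, the collagenase MMP13 fell by 5.57 ± 0.35, NGFR fell by 5.37 ± 0.28 and HAND2 fell by 5.34 ± 0.25. In all, 3957 genes were higher and 3984 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), or 60.6% of those tested. With a change of at least 2-fold also required, 623 were higher and 1215 lower. The groups did not overlap for 37.4% of genes, where chance gives 0.216%. Of the lists 18 were called, 12 higher and 6 lower, and 11 with an estimated correlation. The control vector carries no hairpin, so this comparison holds the effect of any hairpin along with that of PTPN6.

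**Figure D2:**
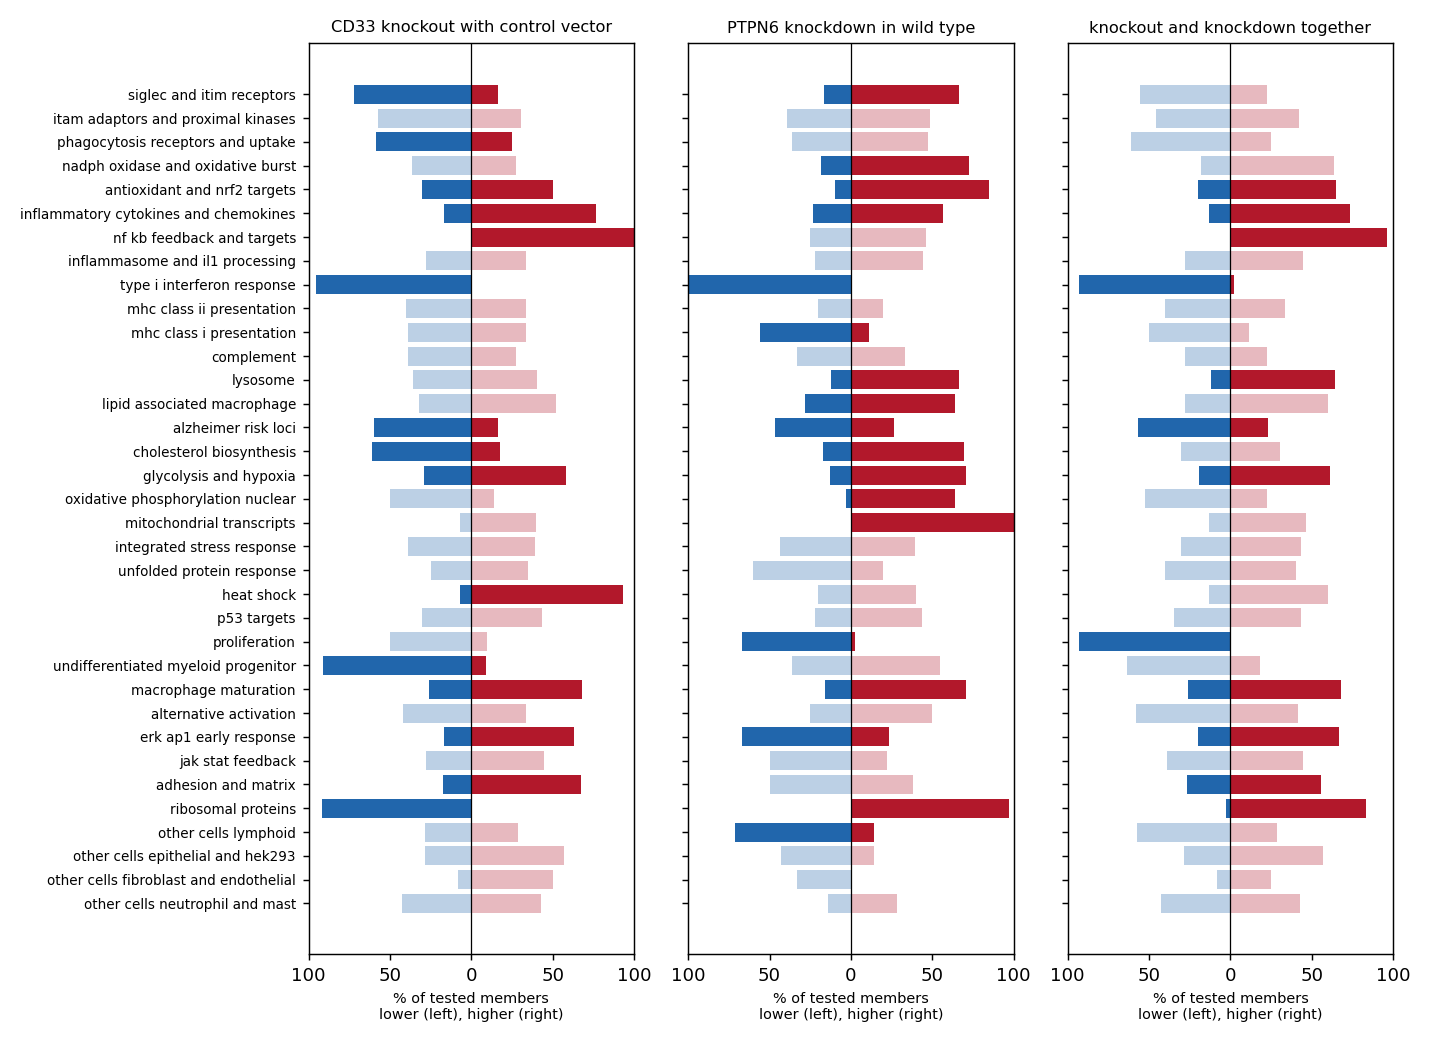
Percent of the tested members of each of the 35 gene lists that were lower (blue, left) or higher (red, right) in the 3 comparisons with WT_shCTRL (edgeR adjusted p under 0.05); pale bars are lists not called by camera. NF-kB targets were higher in 28 of 28 cases in the knockout, and interferon response genes were lower in 45 of 45 cases in the knockdown.

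With knockout and knockdown together, the inflammatory pattern of the knockout was combined with lower proliferation transcripts (n = 5 against 6 in WT_shCTRL). Proliferation genes fell in 39 of 42 cases and rose in none, with a median of -1.34 (camera adjusted p = 2.01e-16). TOP2A, the topoisomerase of dividing cells, went from 306 ± 18.0 to 106 ± 8.16 CPM and the tubulin TUBA1B from 1619 ± 52.0 to 516 ± 24.1 CPM. NF-kB targets rose in 27 of 28 (camera adjusted p = 3.24e-14), and the stress-induced gene IER3 went from 92.0 ± 4.61 to 3369 ± 305 CPM. Cytokines and chemokines rose in 22 of 30 and fell in 4 (camera adjusted p = 1.86e-09), IL23A by 3.63 ± 0.10 and IL1RN by 1.81 ± 0.05. The growth differentiation factor GDF15 rose by 4.64 ± 0.06 (edgeR adjusted p = 5.38e-93).

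Type I interferon response genes fell in 42 of 45 and rose in 1 (camera adjusted p = 1.15e-14; adjusted p = 0.0789 with an estimated correlation), with OAS1 at -1.93 ± 0.08 and XAF1 at -1.81 ± 0.08. Alzheimer's disease risk genes fell in 17 of 30 and rose in 7 (camera adjusted p = 0.00832). BIN1 fell by 5.00 ± 0.10, SORL1 fell by 5.35 ± 0.14 and TREM2 fell by 1.72 ± 0.05. Antioxidant and NRF2 targets rose in 13 of 20 and fell in 4 (camera adjusted p = 0.00158; adjusted p = 0.0921 with an estimated correlation). The cystine transporter SLC7A11 rose by 3.32 ± 0.07 and the autophagy receptor SQSTM1 by 2.47 ± 0.05. Glycolysis and hypoxia genes rose in 19 of 31 and fell in 6 (camera adjusted p = 0.000958; adjusted p = 0.0696 with an estimated correlation), NDRG1 by 2.92 ± 0.05. Lysosome genes rose in 27 of 42 and fell in 5 (27 and 6 adjusted over the list alone; camera adjusted p = 0.00302; adjusted p = 0.0696 with an estimated correlation), and the protease CTSD went from 1045 ± 63.1 to 2706 ± 136 CPM.

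Macrophage maturation genes rose in 21 of 31 and fell in 8 (camera adjusted p = 0.000598), with MMP9 at 2.16 ± 0.05 and CHI3L1 at 1.92 ± 0.05. Adhesion and matrix genes rose in 19 of 34 and fell in 9 (camera adjusted p = 0.00302), with ITGA1 at 4.91 ± 0.10. Early response genes of the ERK and AP1 pathway rose in 20 of 30 and fell in 6 (camera adjusted p = 0.000899; adjusted p = 0.123 with an estimated correlation), with the cyclin CCND1 at 2.00 ± 0.05. Ribosomal protein genes rose in 30 of 36 and fell in 1 (camera adjusted p = 3.33e-06; adjusted p = 0.308 with an estimated correlation). Siglecs and inhibitory receptors were lower for 10 of 18 and higher for 4, and the list was not called (camera adjusted p = 0.282), although CD22 fell by 5.29 ± 0.21. Median, mean and test differed in sign for 4 lists that were not called: ITAM adaptors, complement, alternative activation, and neutrophil and mast cell markers (camera adjusted p = 0.85, 0.827, 0.902 and 0.862).

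The largest rises were again in RPS26P52 (log2 fold change 10.09 ± 0.24), NRG4 (10.01 ± 0.26), CDH13 (9.77 ± 0.24) and HSPG2 (8.86 ± 0.23), with LINC01287 at least 236-fold and the dopamine receptor DRD1 at least 111-fold higher. BBOX1 went from 26.4 ± 3.28 CPM to 0 in each library of the double group, and KRT9 was at least 41.3-fold lower. DPEP1 went from 103 ± 4.40 to 0.345 ± 0.348 CPM, and SAA1 fell by 7.83 ± 0.24. MMP13 fell by 6.62 ± 0.54 and CLIC5 fell by 6.59 ± 0.25. MMP13 was at 0 in the double group except in replicate 6 (0.409 CPM), so its fold rests on very few counts. In all, 4204 genes were higher and 4152 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), or 63.8% of those tested. With a change of at least 2-fold also required, 1220 were higher and 1637 lower. The groups did not overlap for 45.7% of genes, where chance gives 0.433%. Of the lists 12 were called, 9 higher and 3 lower, and 6 with an estimated correlation. Scaling by library size alone would move the median of all genes to -0.144, and all values here are relative to the TMM scale, on which it is near 0.

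In CD33 knockout macrophages, PTPN6 knockdown lowered proliferation genes and raised ribosomal protein and lysosome genes (n = 5 against 6). Proliferation genes fell in 41 of 42 cases, with a median of -0.98 (camera adjusted p = 1.09e-25). Ribosomal protein genes rose in 35 of 36 (camera adjusted p = 2.08e-28) and lysosome genes in 23 of 42, with 5 lower (24 and 5 adjusted over the list alone; camera adjusted p = 1.49e-05). Interferon response genes fell in 18 of 45 and rose in 1 (19 and 1 adjusted over the list alone; camera adjusted p = 0.00575; adjusted p = 0.513 with an estimated correlation). NADPH oxidase genes rose in 7 of 11 and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0267; adjusted p = 0.0718 with an estimated correlation), and CYBB, chosen after its values were seen, went from 20.2 ± 3.16 to 166 ± 14.2 CPM. The largest rises were in IFITM10 (3.67 ± 0.38), the WNT receptor ROR2 (3.43 ± 0.25) and LRRC25 (3.32 ± 0.32), and the largest falls in DMP1 (-3.89 ± 0.22), the deiminase PADI2 (-3.74 ± 0.33) and the cytokine IL11 (-3.67 ± 0.41). In all, 2685 genes were higher and 2827 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), or 42.1%, and 352 and 795 with a change of at least 2-fold. Of the lists 14 were called, 10 higher and 4 lower, but only 3 with an estimated correlation.

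With PTPN6 knocked down in both lines, inflammatory genes were again higher in the CD33 knockout (n = 5 against 6). The lines compared are the same as with control vector, so any other lasting difference between them would return here. NF-kB targets rose in 26 of 28 (camera adjusted p = 6.52e-15), cytokines and chemokines in 25 of 30 with 4 lower (camera adjusted p = 2.45e-11), and ERK and AP1 early response genes in 25 of 30 with 3 lower (camera adjusted p = 1.75e-10). Interferon response genes here rose in 33 of 45 and fell in 5 (34 and 5 adjusted over the list alone; camera adjusted p = 9.8e-05; adjusted p = 0.302 with an estimated correlation). Siglecs and inhibitory receptors fell in 14 of 18 and rose in 2 (camera adjusted p = 0.000472), and proliferation genes fell in 38 of 42 (camera adjusted p = 6.52e-15). Beside these changes mitochondrial transcripts fell in 13 of 15 and rose in 1 (camera adjusted p = 2.95e-05; adjusted p = 0.163 with an estimated correlation). Ribosomal protein genes fell in 24 of 36 and rose in 1 (25 and 1 adjusted over the list alone; camera adjusted p = 0.000272; adjusted p = 0.38 with an estimated correlation). CDH13 (10.34 ± 0.26), NRG4 (10.18 ± 0.27) and RPS26P52 (9.72 ± 0.24) rose most. The chemokine receptor CCR2 was at least 57.9-fold lower, the pepsinogen PGA5 at least 40.6-fold lower, and FCN1 fell by 7.70 ± 0.32. CYBB, again chosen after its values were seen, fell by 1.83 ± 0.06 (edgeR adjusted p = 1.09e-54). In all, 3802 genes were higher and 3599 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), or 56.5%, and 1101 and 1033 with a change of at least 2-fold. Of the lists 12 were called, 6 in each direction, and 8 with an estimated correlation.

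**Figure D3:**
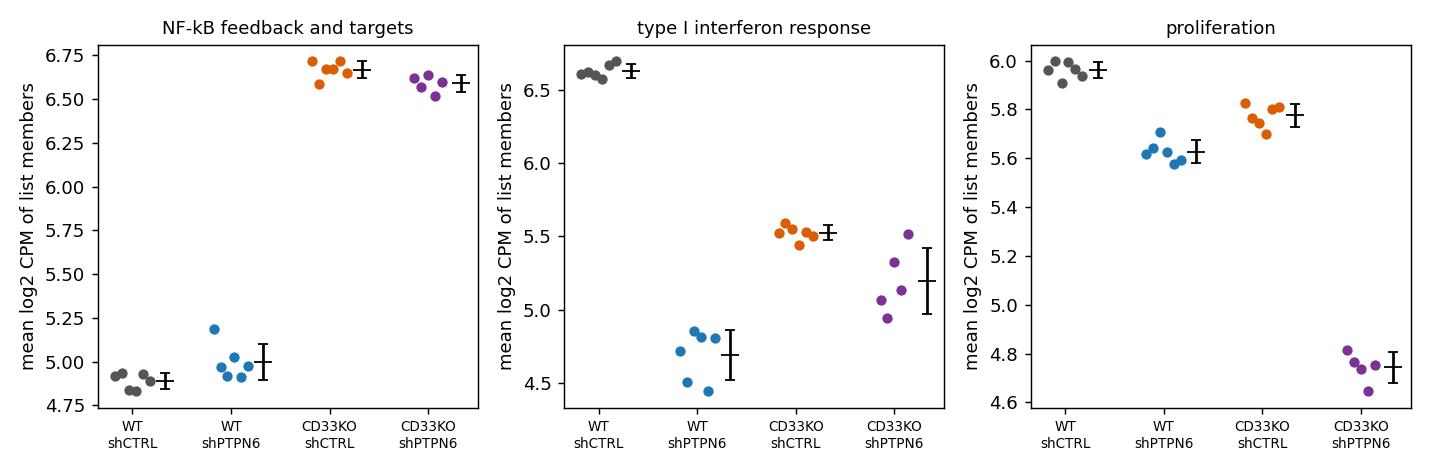
Mean log2 CPM of the tested members of the NF-kB, type I interferon and proliferation lists in each library of the 4 groups; points are libraries, the bar beside them is the mean and the whiskers 1 SD. The interferon list averaged 6.62 in WT_shCTRL, 4.69 in WT_shPTPN6, 5.53 in CD33KO_shCTRL and 5.20 in CD33KO_shPTPN6.

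The interaction asks whether knockdown acted differently in the knockout than in wild type. The interferon response differed most: 43 of 45 genes had a positive difference (44 adjusted over the list alone), with a median of 1.44 (camera adjusted p = 5.72e-35). The fall of the list with knockdown was thus weaker in the knockout. Its mean log2 CPM went from 6.625 to 4.693 in wild type and from 5.525 to 5.198 in the knockout. Proliferation genes went the other way, with 34 of 42 lower and 1 higher and a median of -0.72 (camera adjusted p = 1.96e-17). Mitochondrial transcripts were lower in 15 of 15 (camera adjusted p = 1.97e-11) and maturation genes in 19 of 31 with 4 higher (20 and 4 adjusted over the list alone; camera adjusted p = 1.42e-07). GNLY (4.22 ± 0.10), MMP1 (3.73 ± 0.12), BMP8B (2.47 ± 0.07), the growth factor PDGFA (2.25 ± 0.06) and LMO4 (1.81 ± 0.06) had the smallest adjusted p among positive differences. CDCP1 (-4.93 ± 0.15), fibronectin FN1 (-3.99 ± 0.11), CYP1B1 (-3.34 ± 0.13), APOC1 (-3.08 ± 0.14) and MMP9 (-1.40 ± 0.07) had the smallest among negative ones. GNLY, for example, went from 349 to 8.87 CPM with knockdown in wild type and from 550 to 264 CPM in the knockout, whereas FN1 went from 31.4 to 279 and from 206 to 115 CPM. For CYBB the knockdown effect was larger in the knockout by 1.29 ± 0.10 (edgeR adjusted p = 1.23e-20). In all, 1900 genes were positive and 1817 negative (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), or 28.4%, and 569 and 432 with a difference of at least 2-fold. Of the lists 17 were called, 5 positive and 12 negative, and 9 with an estimated correlation. Among lists that were not called, median, mean and test differed in sign for the ITAM adaptor and phagocytosis lists here. They also differed for the phagocytosis, lipid-associated, mitochondrial, p53, maturation, JAK-STAT, epithelial and neutrophil lists with knockdown in the knockout, and for the inflammasome, lipid-associated, glycolysis, maturation and neutrophil lists with knockout in the knockdown.

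The knockout effects with and without knockdown were correlated across genes. These comparisons share no library but compare the same lines. Across 13098 genes, which are not independent replicates, Pearson's r was 0.783 and Spearman's rho 0.664. Of 5277 genes called in both, 91.1% went the same way, with 2530 higher in both where 1077 are expected and 2277 lower where 1021 are. Not every list kept its direction. The mean log2 CPM of the interferon list was lower in the knockout with control vector (5.525 against 6.625) and higher with knockdown (5.198 against 4.693). The knockdown effect in wild type and in the knockout had r = 0.592 and rho = 0.594, and 90.5% of 4231 genes called in both went the same way. The knockout and the knockdown in wild type resembled each other less. Their effects against the shared WT_shCTRL libraries had r = 0.207 and rho = 0.182, and 62.2% of 4977 genes called in both went the same way. Of these, 1440 were higher in both where 1121 are expected and 1657 lower where 1131 are, while 899 and 981 went opposite ways. Sharing controls alone produces a correlation: simulated unchanged groups had r = 0.431 on average and the same sign in 64.6% of genes, against 0.207 and 56.2% observed. No gene changed in that simulation, so its r and share of signs are not a chance level for these data. The covariance of the simulated groups was 0.00976 against 0.177 observed, and they shared 0 called genes. Fits that gave each effect its own 3 of the control libraries gave r of 0.18 to 0.206. BIN1 and CD22 fell in both, as did 43 and 45 of 45 interferon genes (adjusted p = 0.0565 with an estimated correlation in the knockout), while CYBB moved in opposite directions.

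For the 8356 genes changed by knockout and knockdown together, the combined effect minus the sum of the single effects had a median of -0.028 in the direction of the combined effect (quartiles -0.348 and 0.254). The interaction was called for 2833 of them, 1648 below the sum and 1185 above it. Where both single effects were called in the same direction (2891 genes), the median was -0.349, with 1268 called below the sum and 91 above it. Where they were called in opposite directions (1163 genes), the median was 0.282. Choosing genes by their single effects shifts these medians by itself: in 20 simulated draws with exactly additive effects they were -0.0427 to -0.0294 and 0.031 to 0.0532. At most 1 gene was called below or above the sum in those draws. With no interaction in any gene the adjusted threshold is stricter there, so that count is no reference for the calls in the data.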

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

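The tests of the wild-type traces of HSPG2, NRG4 and CDH13, of other cell types and of depth were chosen only after the result was seen.

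Single libraries far from the rest of their group were found for 50 of 568 groups of values (8.80%), where chance gives about 1 in 20 groups of normally spread values. Where the rest of a group is at 0, as for BPI, SLFN12, FCN1, CCR2 and MMP13 below, any count is flagged by construction. The share is therefore not a clean excess over chance. WT_shCTRL replicate 4 had 7 and replicate 6 had 6, and the other libraries 0 to 4. The values follow, with the lowest and highest of the other libraries of the group in parentheses. WT_shCTRL replicate 2 had INSIG1 at 71.8 CPM (83.2 to 87). WT_shCTRL replicate 3 had DMP1 at 67.6 CPM (50.5 to 55). WT_shCTRL replicate 4 had RPS26P52 at 4.21 CPM (0.172 to 0.932), NRG4 at 5.89 CPM (0 to 1.35), CDH13 at 3.87 CPM (0.409 to 0.9), HSPG2 at 46.6 CPM (16.9 to 20.5), SAA1 at 84.6 CPM (91.7 to 95.6), BPI at 0.337 CPM (0) and the complement list at a mean of 4.65 log2 CPM (4.25 to 4.36). WT_shCTRL replicate 6 had IL23A at 9.55 CPM (7.65 to 8.11), TREM2 at 685 CPM (572 to 613), EGR1 at 48.2 CPM (60.1 to 66.6), CCR2 at 9.55 CPM (4.9 to 6.56), PGA5 at 5.36 CPM (1.43 to 2.76) and PDGFA at 679 CPM (720 to 728).

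WT_shPTPN6 replicate 1 had IER3 at 283 CPM (207 to 229), CCND1 at 452 CPM (397 to 411) and the fibroblast and endothelial marker list at a mean of 2.46 log2 CPM (1.67 to 1.79). WT_shPTPN6 replicate 2 had BMP8B at 113 CPM (117 to 120) and the macrophage maturation list at a mean of 6.37 log2 CPM (6.23 to 6.26). WT_shPTPN6 replicate 3 had HAND2 at 1.41 CPM (0.162 to 0.602). WT_shPTPN6 replicate 4 had FCN1 at 41.5 CPM (45.7 to 47.8) and CDC20 at 104 CPM (118 to 125). WT_shPTPN6 replicate 5 had RPLP0 at 752 CPM (627 to 670) and RPS24 at 4470 CPM (3870 to 4050). WT_shPTPN6 replicate 6 had BCL2A1 at 50.3 CPM (37 to 41.5), NDRG1 at 424 CPM (377 to 392), IL1R2 at 109 CPM (79.7 to 90.1) and FTL at 3430 CPM (3220 to 3300). CD33KO_shCTRL replicate 1 had SAA1 at 2.93 CPM (0 to 0.899), FCN1 at 0.978 CPM (0) and CCR2 at 1.47 CPM (0). CD33KO_shCTRL replicate 2 had LINC01287 at 38.5 CPM (20.2 to 24.9), ANGPTL4 at 72.4 CPM (48.4 to 52.2), ATP5F1B at 368 CPM (394 to 406) and CDC20 at 532 CPM (454 to 471). CD33KO_shCTRL replicate 3 had SLFN12 at 0.45 CPM (0) and CYBB at 26.1 CPM (17.6 to 20.6). CD33KO_shCTRL replicate 5 had a total count of 3749258 (2050000 to 2330000).

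CD33KO_shPTPN6 replicate 1 had CTSH at 245 CPM (208 to 218) and S100A8 at 351 CPM (299 to 312). CD33KO_shPTPN6 replicate 3 had MMP7 at 177 CPM (155 to 161), ATP5F1B at 461 CPM (397 to 414) and the fibroblast and endothelial marker list at a mean of 3.26 log2 CPM (2.54 to 2.72). CD33KO_shPTPN6 replicate 4 had TREM2 at 206 CPM (176 to 182), CHI3L1 at 2200 CPM (2400 to 2470) and TRAC at 121 CPM (88.7 to 90.5). CD33KO_shPTPN6 replicate 5 had NCF4 at 54.6 CPM (38.4 to 42.2) and the alternative activation list at a mean of 2.98 log2 CPM (3.27 to 3.36). CD33KO_shPTPN6 replicate 6 had MMP13 at 0.409 CPM (0).

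The knockdown effect differed between wild type and knockout, by the interaction term of the model, for 17 of 35 lists. With camera adjusted p-values of the difference these were the interferon response (5.72e-35), proliferation (1.96e-17), mitochondrial transcripts (1.97e-11), oxidative phosphorylation (1.49e-08), macrophage maturation (1.42e-07), glycolysis and hypoxia (1.15e-05), NRF2 targets (1.86e-05), ribosomal proteins (1.86e-05), cytokines (2.38e-05), heat shock (4.35e-05) and ERK and AP1 early response (7.78e-05). The others were lymphoid markers (0.00103), MHC class I presentation (0.00226), lipid-associated macrophage genes (0.0038), MHC class II presentation (0.0135), NF-kB targets (0.0256) and lysosome (0.043). With an estimated correlation 9 of these calls held. Those lost were oxidative phosphorylation, early response, MHC class I and lipid-associated genes (adjusted p = 0.0689 each), MHC class II (0.0817), lysosome (0.137), NF-kB targets (0.201) and ribosomal proteins (0.271). Among genes the edgeR adjusted p of the difference was 1.38e-63 for GNLY, 6.58e-56 for PDGFA, 2.38e-55 for BMP8B, 8.49e-54 for CDCP1, 8.21e-53 for MMP1, 2.05e-47 for LMO4, 3.72e-43 for CYP1B1, 1.74e-37 for FN1, 9.7e-38 for APOC1, 1.64e-35 for MMP9 and 3.32e-05 for CD33. A further 59 of 93 named genes also differed. Most of these were named for large changes or small adjusted p-values in other comparisons of the same data. Over all tested genes the interaction was called for 28.4%.

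Regrouping the libraries of each comparison at random gave as many called genes in 1 of 100 splits, the real split itself. For comparisons between a pair of groups, this argues against a random grouping of these libraries. Chance between cultures or transductions was not tested, since the labels do not say whether replicates were separate cultures. Refitted on the compared libraries alone, knockout with control vector gave 7192 genes and knockdown in wild type 7860, and the highest other split gave 0 for both. Knockout and knockdown together gave 8297 against 5597, knockdown in the knockout 5098 against 3148 and knockout with knockdown 7048 against 4637. Those 3 highest other splits have 1 library out of place, so they are nearly the real split. The interaction gave 3717 against 1049, in a split with 14 libraries out of place. Its splits shuffled the vector labels within each line, which takes away the knockdown effects as well. They therefore cannot test the interaction alone, and no conclusion is drawn from them.

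HSPG2, NRG4 and CDH13 summed to 292051, 46786 and 30518 counts in 11 knockout libraries and to 1370, 92 and 63 in 12 wild-type libraries. For HSPG2 alone, WT_shCTRL replicate 4 held 0.431% of the knockout level and the other wild-type libraries 0.151 to 0.318%. Knockout material reaching wild-type libraries is argued against as the whole source of the HSPG2 traces, since their summed ratio to NRG4 was 2.39 times that in knockout libraries (95% interval over resampled libraries 1.73 to 4.34), although WT_shCTRL replicate 4, with a ratio of 7.91, lay close to the 5.81 to 6.87 of knockout libraries. It stays open for NRG4, CDH13 and RPS26P52: the NRG4 to CDH13 ratio gave a Fisher exact p of 0.805 (odds ratio 0.953, 95% interval of counting error alone 0.684 to 1.33), which on so few counts does not show equality, and the limit was narrowed to these genes after the result was seen. One RNA source counted under several names is a candidate explanation for NRG4 and CDH13, whose ratio varied little within knockout groups (chi-square per degree of freedom 1.87, percentile 4.02 of 2415 gene pairs, 1.69 in a first form over all 11 libraries). It is not borne out for HSPG2 with NRG4 (8.46, percentile 62.9) or RPS26P52 with NRG4 (84.1, percentile 95.2), stays undecided for HSPG2 with CDH13 (3.47, percentile 18.9), and a biological difference between the lines stays open, untested.

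In the knockout with control vector 7428 genes, 56.7% of those tested, were called. Lower depth is argued against as the whole cause, since with every library thinned to the smallest total 88.2% of the called genes that were still tested stayed called in the same direction. Copy-number differences between the lines are argued against as the main cause, since 10-Mb windows explained 4.34% of the variance of fold changes beyond shuffled genes. RNA of another cell type may contribute and stays open: the lowest adjusted p of its lists was 0.0651, which excludes nothing, and members went both ways (TIE1 to 49.1 CPM, INA to 0.276 CPM). Loss of CD33 and any other lasting difference between the lines stay open as biological explanations, untested against each other.

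In the knockdown in wild type 7941 genes, 60.6% of those tested, were called. Depth is argued against as the whole cause, since 83.8% of the called genes still tested stayed called after thinning. Direct matches of the hairpin guide are argued against as the main cause, since the site GAGAACA was in the 3' UTR of 16.5% of the lower genes with one, against 14.3% of higher genes and 14.4% of those not called. Its mean effect ranked 70 of 105 sites of the same composition, from the most negative. Loss of PTPN6 stays open as a biological explanation, as does a general effect of expressing a hairpin, which the empty vector does not control for and which was not tested.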

How the results depend on the processing

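Thinning all libraries, leaving out WT_shCTRL 4, WT_shPTPN6 3 and CD33KO_shCTRL 2, and leaving out the library of each group with the most genes outside the rest (WT_shCTRL 4 with 11, WT_shPTPN6 5 with 14, CD33KO_shCTRL 2 with 60, CD33KO_shPTPN6 3 with 43) are tests chosen after the data were seen. WT_shPTPN6 3 was taken for its knockout transcripts, but it had 0 such genes and less HSPG2 than WT_shPTPN6 5 (0.27 and 0.318% of the knockout level). Counts of called genes in each direction stayed within 1.5 times under other size factors, DESeq2, other filters, a model of the compared groups alone, thinning, the 3 or 4 libraries left out and each replicate left out, and no gene was called in the opposite direction. Adding a 2-fold minimum left 1018 higher and 1037 lower genes for knockout with control vector, 623 and 1215 for knockdown in wild type, 1220 and 1637 for both together, 352 and 795 for knockdown in the knockout, 1101 and 1033 for knockout with knockdown and 569 and 432 for the interaction, since that setting takes away small changes by construction. With an estimated correlation 11 lists stayed called for knockdown in wild type, 6 for both together, 3 for knockdown in the knockout and 9 for the interaction. Why fewer lists were called was not tested. With fry, which does not compare a list with other genes, 32, 32, 32, 28, 30 and 27 lists were called in the order of the comparisons. Restricting to genes of at least 10 CPM moved the correlation of the knockout effects to 0.788 and that of the knockdown effects to 0.636, and the cause was not tested. Without the 3 libraries the lists called numbered 16, 18, 12, 17, 13 and 17, which kept 15, 18, 12, 14, 12 and 16 of those called with all, and without the 4 they numbered 16, 19, 13, 15, 12 and 17, which kept 15, 18, 12, 13, 12 and 16. Thinning to 2024032 counts kept 88.2, 83.8, 92.2, 93.2, 90.8 and 81.4% of the called genes still tested.

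Of 2417 values of 162 pairs of a named gene and a comparison, 2406 kept their side of the threshold and none changed direction. PTPN6 in the knockout with control vector lost its call with DESeq2 (0.0747), after thinning (0.0636), without the 3 (0.0634) or the 4 libraries (0.0761) and without replicate 3 (0.118) or 6 (0.203), over a range of 0.0217 to 0.203. PTPN6 in the knockout with knockdown lost it after thinning (0.102) and without replicate 1 (0.0856), 4 (0.0544) or 6 (0.0825), over a range of 0.00344 to 0.102. CD33 with knockdown in the knockout passed without replicate 4 (0.0343), over a range of 0.0343 to 0.548. The cause was not tested. All of these are edgeR or DESeq2 adjusted p-values.

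The replicate numbers do not pair the libraries. Over 33 pairs with the same number, deviations from the group means had correlations of -0.0493 to 0.0324, and 3 of 23 libraries correlated best with one of their own number. With a replicate block the counts were 3683 and 3679, 3918 and 3960, 4150 and 4120, 2630 and 2770, 3754 and 3540, and 1862 and 1764 genes higher and lower, with 15, 18, 12, 13, 12 and 17 lists called. The correlations were then 0.783, 0.592 and 0.206.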

Other observations

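The test of chromosome segments was chosen after the result was seen, as were the genes IL1RN, IL1B, VGF and CRTC2 as examples. Some gene groups moved in comparisons where the text has not yet described them. With PTPN6 knocked down in both lines, nuclear genes of oxidative phosphorylation fell with CD33 knockout in 30 of 36 cases and rose in 2 (31 and 2 adjusted over the list alone; camera adjusted p = 4.25e-08; adjusted p = 0.0982 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 23 and rose in 3 (camera adjusted p = 0.000157). Feedback genes of the JAK-STAT pathway rose in 11 of 18 and fell in 1 (camera adjusted p = 0.00606). In the interaction, heat shock genes were lower in 10 of 15 (11 adjusted over the list alone; camera adjusted p = 4.35e-05) and cytokines and chemokines lower in 17 of 30 and higher in 6 (camera adjusted p = 2.38e-05). For IL1RN the rise with knockout was 6.43-fold with control vector and 3.23-fold with knockdown, and for IL1B it was 10.9-fold and 7.75-fold.

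CD33KO_shCTRL replicate 2 differed from the other 5 libraries of its group by at least 2-fold in 60 genes, more than any other library (CD33KO_shPTPN6 replicate 3 had 43 and replicate 1 had 37). VGF, a secreted neuropeptide precursor, stood at 90.8 CPM there and at 7.81 ± 2.79 CPM in the other 5, and CRTC2, a transcription coactivator, at 7.33 and 60.5 ± 16.6 CPM.

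Genes on chromosome 12 were lower in the knockout as a set. The median log2 fold change of its 705 tested genes was -0.396 with control vector, with 77.2% of them below 0, and in the first 30 Mb of chromosome 6 (120 genes) it was 0.736, with 87.5% above 0, while 11632 genes on other chromosomes had a median of 0.00681. The rest of chromosome 6 (558 genes) had a median of 0.0486, but its 10-Mb windows went both ways, from 0.400 to -0.519. A hypothesis is that copy number of these segments differs between the lines. With knockdown, in libraries that share none with the first comparison, the medians were -0.439 and 0.831, and they were 0.0255 and -0.0756 for knockdown in wild type and -0.0084 and -0.0766 for knockdown in the knockout. These values go with the hypothesis, but the segments were picked from the first knockout comparison and any lasting difference between the lines would return in the second one, so they say little about copy number in particular. PTPN6 lies on chromosome 12, and its fall of 15% in the knockout with control vector may share this shift. That fall (log2 fold change -0.23) was smaller than the median of -0.75 of the 82 genes in the 10-Mb window that holds it.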
